A study of Danio rerio with 6 samples.

How the data were processed

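Total RNA was extracted with Trizol from zebrafish tumours, and RNA with an integrity number of at least 7 went into stranded, paired-end total RNA libraries that were sequenced on an Illumina HiSeq instrument, per the labels' protocols. Reads were processed by the authors with TopHat2 2.0.14, Bowtie2 2.2.6, Subread and featureCounts 1.4.6 on the danRer10 build, per the submitters' processing notes. The strand setting, the gene annotation and the treatment of multiply mapped reads are not given in the sources used here, so reads of overlapping or antisense genes, and of near-identical copies, cannot be told apart with certainty. The deposited values are whole-number counts per gene symbol, not normalized. The table held 14781 symbols, 508 of them at 0 in all libraries, and no column without a sample. Of the symbols, 14519 matched a symbol or synonym of the RefSeq gene table of assembly GRCz12tu, which differs from the build of the counts and was used only for names and for the order of genes along chromosomes.

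The 6 libraries were grouped by genotype as the labels give it, with 3 knockout and 3 MYCN-only libraries. Genes with low counts were removed with filterByExpr, which left 12821 genes, and the counts were scaled by TMM. The main test was edgeR's quasi-likelihood F test with genotype as the only term and a Benjamini-Hochberg adjusted p under 0.05. The biological coefficient of variation was 52.5%. Standard errors of log2 fold changes were taken from the fold change and its F statistic. CPM values use TMM-scaled library sizes, and log2 CPM has a prior count of 2. A list's level in a library is the mean log2 CPM of its members. Total counts ran from 12054844 to 33305326, and the 10 most counted genes took 9.45% to 14.9% of the counts of a library.

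There were 40 gene lists, 20 of pathways and 20 of cell types. They were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 40 lists together, beside camera with an estimated correlation and fry. The lists, the tests and the other settings listed below were fixed before the data were examined. List members missing from the table under their symbol were matched through synonyms. This was introduced after a first run with exact symbols, in which 19 lists passed, and exact matching is given as an alternative. The genes named follow a rule fixed beforehand: gas7, mycn, myca and mycb genes, the strongest genes past the threshold or, with fewer than 5 of these, the 10 with the smallest unadjusted p, and up to 4 members with the smallest p of each list that passed and of 6 lists of interest. No gene qualified by threshold, so the 10 with the smallest p were taken, leaving out placeholder symbols. Examples were drawn from these genes. Genes named outside the rule are said to be so.

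The test was tried on simulated counts for knockout against MYCN-only, with the gene means and library sizes of these data and 200 changed genes. At the spread fitted here, over 12692 tested genes, the test recovered 0% of genes changed 2-fold, 14.9% of those changed 4-fold and 84.8% of those changed 16-fold, with 6 false calls. At a coefficient of variation of 20%, over 12775 genes, it recovered 67.2%, 98.5% and 100%, with 3 false calls. The list test was tried on simulated counts in which genes varied independently and 50 genes were shifted by 0.7 log2 units. In the data, members of a list varied together, with estimated correlations from 0.0191 (cadherins) to 0.829 (cell cycle). The simulation therefore does not test how often such lists are falsely called. At the spread fitted here, over 12705 genes, camera called the shifted list (adjusted p = 9.45e-11) and 0 of the 40 unshifted ones, and at a coefficient of variation of 20%, over 12775 genes, it did so as well (adjusted p = 5.79e-52; 0 of 40).

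Alternatives were DESeq2 size factors and upper-quartile factors in edgeR, other low-count filters, robust dispersion, DESeq2, limma-voom, a minimum fold change, the replicate number as a block and leaving out each library. A fit with knockout libraries 2 and 3 left out was added after seeing the data. It assumes that the lone knockout library varies like the MYCN-only libraries. Also added then were a fit with the ovary list mean as a covariate, and exact symbol matching. That covariate sets knockout libraries 2 and 3 apart, so the genotype term of its fit rests mainly on knockout library 1. For ctsba and rbp2a, log2 fold changes were 2.7 and -3.88 in knockout library 1 alone and 2.65 and -4.03 with the covariate. No pair of libraries agreed within sampling noise (chi-square per degree of freedom of at least 65.2), so none was counted as a duplicate. The share of genes with the same direction in comparisons that share the MYCN-only libraries was set beside 20 simulated draws with knockout library 1 unchanged, at the dispersion fitted without that library. Analyses used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.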

Results

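The series measured the RNA of zebrafish neuroblastomas, tumours of the peripheral sympathetic nervous system that arise in transgenic fish overexpressing the oncogene MYCN. Tumours of fish carrying MYCN alone (MYCN-only, 3 libraries) were compared with tumours of fish carrying MYCN together with a knockout of gas7 (knockout, 3 libraries). GAS7 is an F-BAR protein that binds membranes and actin, and the series title places the comparison in the question of how its loss affects the spread of MYCN-driven neuroblastoma. The table held counts for 14781 gene symbols, of which 12821 passed the low-count filter and were tested. Total counts were 20310441, 25202450 and 33305326 in knockout libraries 1, 2 and 3, and 15256412, 12054844 and 16624086 in MYCN-only libraries 1, 2 and 3. Every knockout library was thus deeper than every MYCN-only library (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). The labels do not say in so many words that the replicates are separate fish, so p-values measure the spread between these samples.

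The labels name gas7 and do not say which copy of the gene was targeted. gas7a was read at 14.8, 13.9 and 10.03 CPM (counts scaled to a common library total) in knockout libraries 1, 2 and 3 and at 23.0, 9.69 and 32.7 CPM in the MYCN-only libraries, with a log2 fold change of -0.76 (SE 0.47; edgeR quasi-likelihood adjusted p = 0.411). The ranges overlapped, since MYCN-only library 2 had the lowest level of all 6. gas7a was the only symbol of the table starting with gas7, and gas7b was not analysed here. The labels do not describe the mutation, and a mutated gene can still be transcribed, so this level does not check the genotype labels. The endogenous mycn gene stood at 1.81 ± 0.457 CPM (SD, n = 3) in knockout and 4.52 ± 1.2 CPM in MYCN-only tumours, a log2 fold change of -1.32 that did not pass (edgeR adjusted p = 0.215). Its relative mycb stood at 25.8 ± 5.77 against 10.5 ± 3.69 CPM (log2 fold change 1.3, edgeR adjusted p = 0.187), and myca at 11.2 ± 7.48 against 9.21 ± 1.04 CPM. The MYCN transgene itself was not analysed here.

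Single genes were then compared between the genotypes. The lysosomal protease gene ctsba (cathepsin B) had the smallest p, at 658 ± 56.0 CPM in knockout and 94.9 ± 16.5 CPM in MYCN-only tumours (SD, n = 3), a log2 fold change of 2.79 (SE 0.24; edgeR adjusted p = 0.127). The retinol-binding protein gene rbp2a lay in the other direction, at 20.6 ± 6.31 against 209 ± 15.8 CPM (log2 fold change -3.34, SE 0.31). Higher in all 3 knockout libraries than in any MYCN-only library were also bzw1b (log2 fold change 1.85), the polo-like kinase gene plk3 (3.56), manf, which encodes a stress-induced protein of the endoplasmic reticulum (2.92), the tetraspanin gene tspan36 (2.13) and the cathepsin gene ctssb.1 (5.24). Lower in all 3 were arg1, which encodes arginase (-2.45), the polyamine acetyltransferase gene sat1a.1 (-2.31) and ppp1r1c (-3.07). None of these 10 genes, those with the smallest unadjusted p, passed in edgeR's test over all 6 libraries (adjusted p = 0.127 to 0.174). All 10 passed in DESeq2 and in edgeR without knockout library 1 (adjusted p = 0.000738 to 0.0124), 4 in edgeR with the ovary list mean as a covariate, a fit chosen after seeing the data, and 1 (ctsba) in limma-voom, each in the same direction.

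edgeR's quasi-likelihood test called 0 genes at an adjusted p under 0.05, with 0 higher and 0 lower. At an unadjusted p under 0.05 there were 2447 genes, 1476 higher and 971 lower in knockout, where chance gives 641. The other 9 splits of the libraries into 3 against 3 gave 163 to 1888 such genes, the highest 3 in the splits that keep knockout libraries 2 and 3 together. The libraries of the genotypes did not overlap for 23.9% of the tested genes (1487 higher and 1575 lower), against the 10% that chance gives for 3 against 3. DESeq2 called 1360 genes on the same counts (850 higher, 510 lower) and limma-voom 1, ctsba. Without knockout library 1, edgeR called 1923 genes (1465 higher, 458 lower). Of the 1831 of these that were also tested with knockout libraries 2 and 3 left out, 60.9% had the same direction in knockout library 1. Both comparisons use the same MYCN-only libraries, and 20 simulated draws in which knockout library 1 was unchanged from MYCN-only, with genes varying independently, gave 58.3% on average (56.8% to 59.8%). The observed share lay above every draw, but the draws called 2534 to 2723 genes, against 1923, and left out genes varying together. They therefore do not decide whether knockout library 1 shared the change. Without MYCN-only library 2 edgeR called 4, all lower: apoea, cd36, slc15a1b and zgc:154142, of which all but slc15a1b were named after their values were seen.

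**Figure D1:**
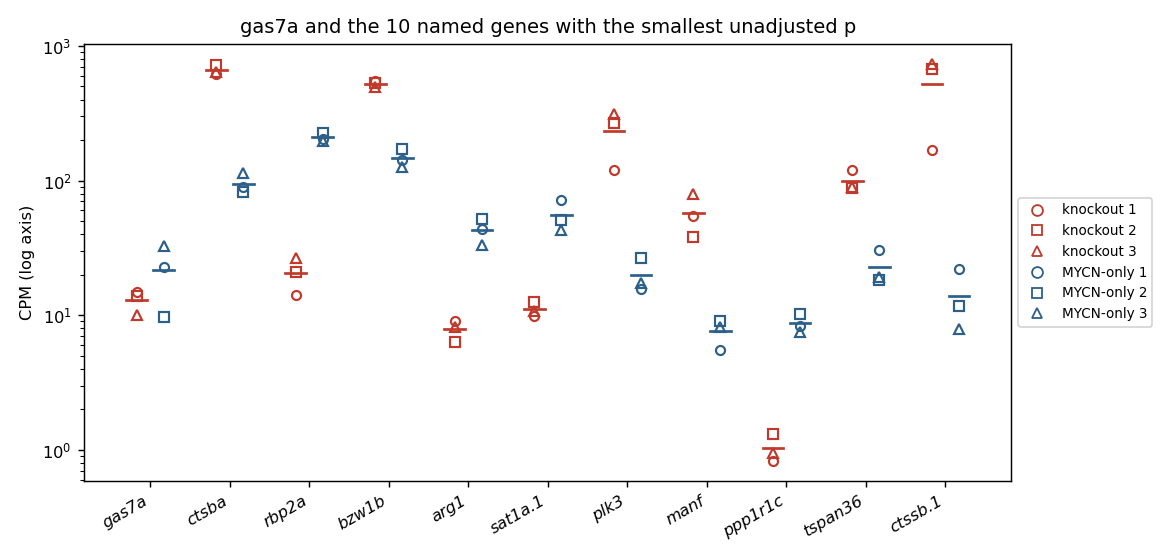
Level of gas7a and of the 10 genes with the smallest unadjusted p in each library, in CPM on a log axis, with a line at the mean of each genotype (n = 3). The libraries of gas7a overlap between genotypes, while ctsba lies between 616 and 722 CPM in knockout and between 82.0 and 114 CPM in MYCN-only tumours.

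Egg and ovary transcripts set knockout libraries 2 and 3 apart from the other 4. The egg coat gene zp2.1 was read at 528 and 677 CPM in knockout libraries 2 and 3, at 2.08 CPM in knockout library 1 and at no more than 0.120 CPM in the MYCN-only libraries. The germ-cell gene nanos3 stood at 36.9 and 45.8 CPM in knockout libraries 2 and 3, against 0.986 CPM in knockout library 1. Of 23 measured members of the ovary and oocyte list, 22 were higher in knockout, with a median log2 fold change of 7.48, and 18 of them passed when adjusted over the list alone. The remaining member, the follistatin gene fsta, named after its values were seen, passed as lower over the list alone, at 4.38 ± 0.891 against 12.9 ± 6.72 CPM (SD, n = 3). The mean log2 CPM of the whole list was 7.42 and 7.83 in knockout libraries 2 and 3 and 0.88 in knockout library 1. In the MYCN-only libraries it lay between -0.63 and -0.04. The list rose in camera with a preset correlation (adjusted p = 1.23e-12), and the call was lost with an estimated correlation (adjusted p = 0.487). With knockout libraries 2 and 3 left out, a choice made after seeing the data, the list still passed as higher (camera adjusted p = 0.000447), with a median log2 fold change of 1.92 in knockout library 1. Egg coat genes are members of families of similar copies, between which the counting could have divided reads.

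The same arrangement of libraries appeared in the most variable genes. The first principal component of the 1000 most variable genes held 64.8% of the variance and placed knockout libraries 2 and 3 at 82.7 and 93.2, knockout library 1 at -25.2 and the MYCN-only libraries between -54.1 and -44.6. The second component held 17% and placed knockout library 1 highest, at 56.8. Across genes, which are not independent replicates, log2 CPM correlated at 0.946 between knockout libraries 2 and 3. Knockout library 1 correlated at 0.781 and 0.764 with these and at 0.843 to 0.858 with the MYCN-only libraries.

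**Figure D2:**
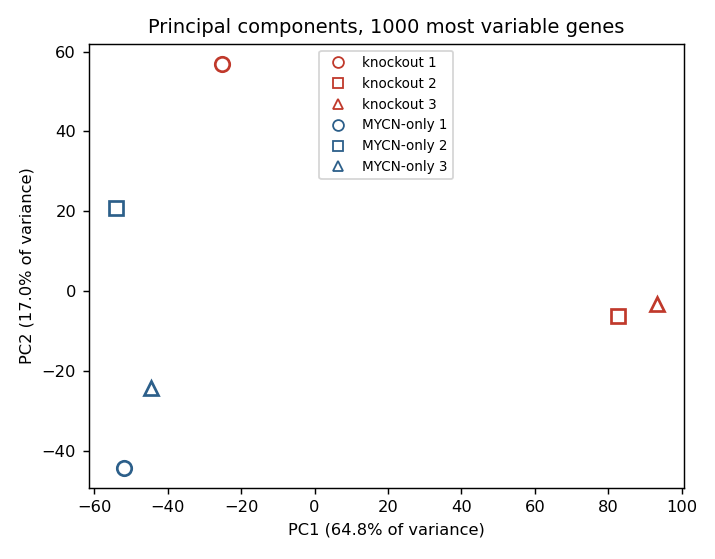
Position of the 6 libraries on the first and second principal components of log2 CPM over the 1000 most variable genes, in component units, with the share of variance on each axis. Knockout libraries 2 and 3 lie at 82.7 and 93.2 on the first component, and knockout library 1 lies at -25.2, nearer to the MYCN-only libraries.

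Cell cycle genes were higher in knockout libraries 2 and 3 than in the other 4. The cyclin genes ccnb1 and ccnb2, which drive entry into mitosis, were read at 806 and 315 CPM in knockout library 2 and at 1029 and 389 CPM in knockout library 3. In knockout library 1 they stood at 17.9 and 2.18 CPM, and in MYCN-only library 1 at 14.5 and 1.98 CPM. The cell cycle list and the ovary and oocyte list share 1 gene, ccnb1, so its level is not separate from the ovary result. The histone gene h2afx had 142 ± 100 CPM in knockout and 15.9 ± 6.64 CPM in MYCN-only tumours (SD, n = 3), and the kinase gene cdk2 19.7 ± 6.97 against 6.69 ± 1.0 CPM. Of 94 measured members of the cell cycle and mitosis list, 91 were higher, with a median log2 fold change of 1.85, and 0 passed in edgeR when adjusted over all genes or adjusted over the list alone, with 61 higher at an unadjusted p under 0.05. Over all genes, edgeR without knockout library 1 called 82 as higher, DESeq2 42 and limma-voom 0. The list mean was 6.06 and 6.24 log2 CPM in knockout libraries 2 and 3, 3.35 in knockout library 1 and 3.34 to 3.80 in the MYCN-only libraries. The list rose in camera with a preset correlation (adjusted p = 1.1e-18) but not with an estimated one (adjusted p = 0.487). With knockout libraries 2 and 3 left out, a choice made after seeing the data, the direction turned to lower, with a median log2 fold change of -0.33. With the ovary list mean as a covariate the median was -0.87, and the list passed as lower with the preset correlation (camera adjusted p = 6.29e-09). The list mean of knockout library 1 nevertheless lay within the range of the MYCN-only libraries. The covariate fit also rests mainly on knockout library 1, so it is not a second check.

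Genes of the extracellular matrix were lower in knockout tumours. The basement membrane collagen genes col4a5 and col18a1 stood at 6.29 ± 0.650 and 28.7 ± 2.25 CPM in knockout against 24.3 ± 5.94 and 143 ± 62.5 CPM in MYCN-only tumours (SD, n = 3). The collagen-binding glycoprotein gene sparc stood at 29.9 ± 7.90 against 132 ± 50.3 CPM. The tenascin gene tnr went the other way, at 37.6 ± 17.5 against 5.40 ± 1.63 CPM. Of 50 measured members of the list of collagens and structural extracellular matrix, 45 were lower, with a median log2 fold change of -1.01, and in 23 every knockout library lay below every MYCN-only library. When adjusted over the list alone, 5 passed in edgeR as lower and 1 as higher, and 0 passed over all genes, with 20 lower and 1 higher at an unadjusted p under 0.05. Over all genes, edgeR without knockout library 1 and DESeq2 each called 9 as lower and 1 as higher, and limma-voom called 0. The list fell in camera with a preset correlation (adjusted p = 2.17e-10), and its adjusted p was 0.453 with an estimated correlation. Its mean was lower in knockout library 1 (3.38 log2 CPM) and in knockout libraries 2 and 3 (3.86 and 3.08) than in the MYCN-only libraries (4.23 to 5.02). The call held with knockout libraries 2 and 3 left out (camera adjusted p = 3.38e-05). Markers of fibroblasts and mural cells, a list that shares 3 measured genes with this one (postnb and, outside the rule for named genes, dcn and lum), fell as well (14 of 20 lower, camera adjusted p = 0.000881, and adjusted p = 0.487 with an estimated correlation). Among them the smooth muscle actin gene acta2 stood at 21.9 ± 21.1 against 99.5 ± 45.7 CPM.

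Receptors and ligands that guide axons and cells were lower as a group as well. The netrin receptor gene unc5b stood at 14.2 ± 2.87 CPM in knockout and 39.8 ± 2.24 CPM in MYCN-only tumours (SD, n = 3), and the plexin gene plxna4 at 206 ± 21.1 against 466 ± 38.3 CPM. Of 43 measured genes of axon guidance and neural migration, 34 were lower (median log2 fold change -0.54), and 2 passed when adjusted over the list alone. In camera the list fell with a preset correlation (adjusted p = 7.78e-05), with an adjusted p of 0.453 with an estimated correlation. Of 33 integrin and focal adhesion genes, 26 were lower, among them itgb3b (log2 fold change -1.83) and itgb4 (-2.49), also a member of the epidermis list. The integrin and focal adhesion list fell with the preset correlation (camera adjusted p = 0.000881, and adjusted p = 0.487 with an estimated correlation). The TGF-beta and BMP list fell too (39 of 49 lower, camera adjusted p = 0.000502, and adjusted p = 0.453 with an estimated correlation), although its members id3 and id2a, which encode BMP-induced inhibitors of differentiation, had log2 fold changes of 1.07 and 0.92. The Wnt list (40 of 53 lower, camera adjusted p = 0.00194) had fzd10, a frizzled receptor gene, at -2.2 and an adjusted p of 0.453 with an estimated correlation. With the ovary list mean as a covariate, the calls of axon guidance, integrins, TGF-beta and Wnt were lost (camera adjusted p = 0.152, 0.0569, 0.443 and 0.0569). Their median log2 fold changes went from -0.54 to -0.36, from -0.36 to -0.63, from -0.54 to -0.11 and from -0.42 to -0.59, and the median SE of their genes from 0.411 to 0.528, from 0.387 to 0.497, from 0.475 to 0.566 and from 0.521 to 0.615. With knockout libraries 2 and 3 left out, the median log2 fold change was -0.44 for axon guidance and -0.55 for integrins. It was -0.59 for Wnt and -0.4 for TGF-beta, whose call was lost.

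Genes of noradrenergic identity did not pass as a group, and the knockout libraries lay on both sides of the MYCN-only libraries. Of 21 measured members, 11 were higher and 10 lower (median log2 fold change 0.01, camera adjusted p = 0.22). The list mean was 7.42 log2 CPM in knockout library 1, 6.12 and 6.32 in knockout libraries 2 and 3 and 6.57 to 6.98 in the MYCN-only libraries. Without knockout library 1 the list fell (camera adjusted p = 0.0218), while it rose with knockout libraries 2 and 3 left out (0.0376) and with the ovary covariate (0.0137). The catecholamine enzyme gene ddc stood at 168 ± 73.1 CPM in knockout and 625 ± 179 CPM in MYCN-only tumours (SD, n = 3) and passed when adjusted over the list alone, though not over all genes (edgeR adjusted p = 0.174). The transcription factor genes tfap2a and phox2a had log2 fold changes of -1.12 and -1.13 and were lower in every knockout library. The members th, dbh and chga, named outside the rule, had log2 fold changes of 0.45, 0.08 and 2.27. They did not pass either (edgeR adjusted p = 0.539, 0.941 and 0.348). The value of chga came from knockout library 1, where it was read at 291.8 CPM. In knockout libraries 2 and 3 it stood at 13.15 and 16.25 CPM, below all MYCN-only libraries (17.42 to 28.18 CPM). The list of neuronal differentiation and synapse fell (22 of 27 lower, median -0.41, camera adjusted p = 0.0331), with an adjusted p of 0.487 with an estimated correlation. Its member uchl1, a neuronal ubiquitin hydrolase gene, was higher, at 324 ± 53.6 against 84.8 ± 28.9 CPM. That call was lost without knockout library 2 or 3 (camera adjusted p = 0.106 and 0.0949). Of 97 actin cytoskeleton regulators, 45 were higher and 52 lower (median -0.05, camera adjusted p = 0.581), and the beta-actin gene actb1 stood at 1928 ± 476 against 936 ± 68.6 CPM. Of 26 matrix proteases and inhibitors, 18 were higher (camera adjusted p = 0.431), and ctsba alone passed when adjusted over the list alone.

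**Figure D3:**
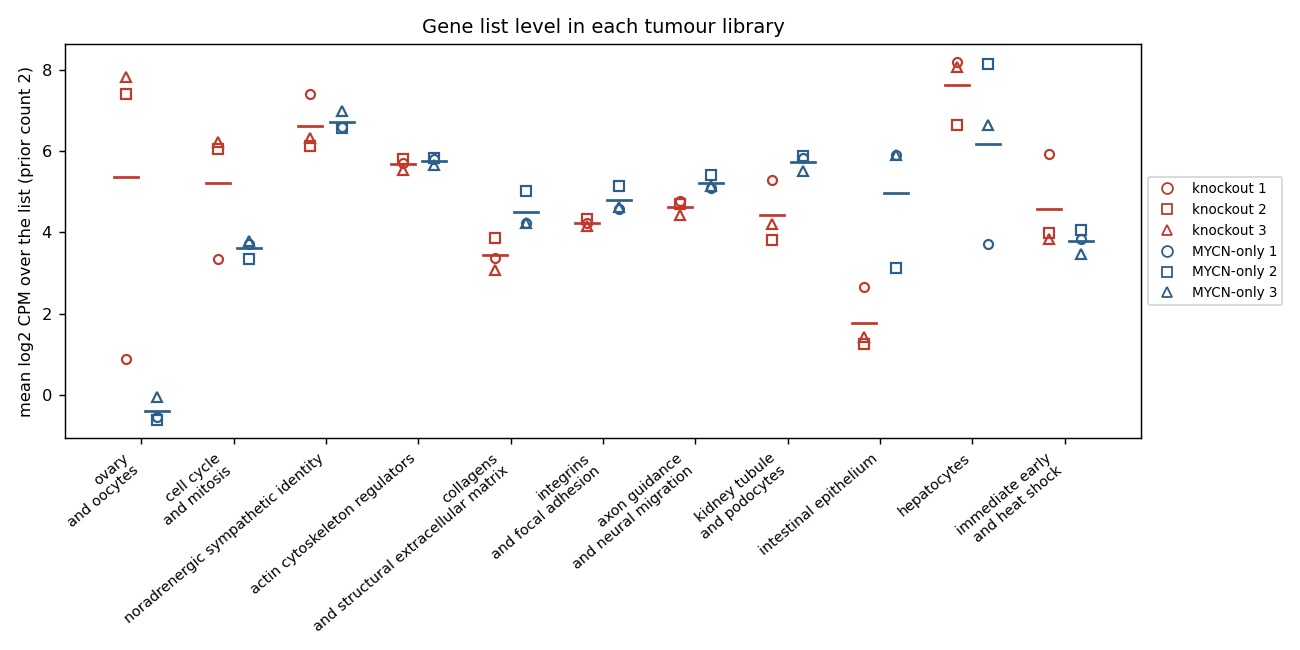
Mean log2 CPM (prior count 2) of 11 gene lists in each library, with a line at the mean of each genotype (n = 3). The ovary list stands at 7.42 and 7.83 in knockout libraries 2 and 3 and at 0.88 in knockout library 1, and the matrix list is lower in every knockout library (3.08 to 3.86) than in the MYCN-only libraries (4.23 to 5.02).

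Markers of other tissues were mostly lower in knockout tumours. All 21 measured intestinal genes were lower (median log2 fold change -3.08), for example vil1, which encodes the microvillus protein villin, at 5.45 ± 3.2 against 81.4 ± 41.0 CPM (SD, n = 3). The list means spread within MYCN-only, at 5.90, 3.11 and 5.91 log2 CPM in libraries 1, 2 and 3. Pancreas genes (21 of 24 lower, median -2.49) included cpa5 at 19.8 ± 12.3 against 123 ± 56.3 CPM. Kidney genes (27 of 30 lower, median -1.44) included pdzk1, which encodes a scaffold of tubule transporters, at 33.5 ± 22.5 against 163 ± 31.0 CPM. When adjusted over the list alone, 13 intestinal, 14 pancreas and 3 kidney genes passed as lower. The 3 lists fell in camera with a preset correlation (adjusted p = 1.83e-12, 6.39e-12 and 1.1e-10), and each had an adjusted p of 0.453 with an estimated correlation. With the ovary covariate the kidney call was lost (camera adjusted p = 0.237), its median going from -1.44 to -0.44 and the median SE of its genes from 0.587 to 0.728, while intestine (0.0137) and pancreas (2.87e-11) passed.

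The remaining lists of other cell types that fell, each with an estimated-correlation adjusted p of 0.487 unless given, were epidermis (17 of 19 lower, camera adjusted p = 1.12e-06), erythroid cells (17 of 18, 6.84e-06), Schwann and neural crest cells (17 of 21, 1.49e-05) and ciliated cells (18 of 22, 7.63e-05). Fibroblasts and mural cells (14 of 20, 0.000881) and cardiomyocytes (10 of 13, 0.00365) fell as well. The neural crest regulator gene sox10 stood at 1.33 ± 0.556 against 7.60 ± 3.41 CPM (SD, n = 3). Skeletal muscle genes fell (36 of 45 lower, camera adjusted p = 0.000393, and adjusted p = 0.673 with an estimated correlation), but MYCN-only library 2 held the highest level, with a list mean of 6.03 against 3.79 and 2.33 log2 CPM, and without it the call was lost (camera adjusted p = 0.8). Ribosomal protein genes fell by a small amount (78 of 79 lower, median -0.28, camera adjusted p = 0.00114, and adjusted p = 0.673 with an estimated correlation). With knockout libraries 2 and 3 left out, epidermis, Schwann and neural crest, muscle and cardiomyocyte calls were lost. Their medians in knockout library 1 were -1.66, -1.07, -1.65 and -1.72, against -2.2, -1.19, -1.62 and -1.29 over all libraries. TGF-beta and BMP, fibroblast, ribosomal protein and neuronal differentiation calls were lost as well. Those medians were -0.4, -0.52, -0.09 and -0.07, against -0.54, -1.24, -0.28 and -0.41. With the ovary covariate, epidermis, Schwann and neural crest, muscle, fibroblast, ribosomal protein, cardiomyocyte and neuronal differentiation calls were lost (camera adjusted p = 0.481, 0.237, 0.812, 0.897, 0.746, 0.237 and 0.746), and the camera direction of the fibroblast and neuronal lists turned to higher although their medians stayed negative. Their medians went from -2.2 to -1.4, from -1.19 to -0.77, from -1.62 to -1.42, from -1.24 to -0.41, from -0.28 to -0.03, from -1.29 to -1.35 and from -0.41 to -0.04, with a larger median SE in each.

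The list of immediate early and heat shock genes had its highest mean in knockout library 1. The nuclear receptor gene nr4a1 was read at 361 CPM in that library, at 31.4 and 36.2 CPM in knockout libraries 2 and 3 and at 2.31 to 6.43 CPM in MYCN-only tumours, and the chaperone gene hsp70.1 at 123 CPM against 15.6 and 10.4 CPM in the other knockout libraries. Of 39 members, 29 were higher, and dnajb1b and btg2 had log2 fold changes of 2.78 and 1.82. The chaperone gene dnajb1b was lowest among the knockout libraries in library 1, at 26.3 CPM against 47.7 and 75.3 CPM in libraries 2 and 3. The list mean was 5.93 log2 CPM in knockout library 1, 3.98 and 3.84 in knockout libraries 2 and 3 and 3.48 to 4.06 in MYCN-only tumours. The list rose (camera adjusted p = 0.00194, and adjusted p = 0.673 with an estimated correlation), and without knockout library 1 the call was lost (camera adjusted p = 0.825). Macrophage genes rose at the edge of the threshold (17 of 20 higher, camera adjusted p = 0.0481, and adjusted p = 0.673 with an estimated correlation). That call was lost without knockout library 1 (0.825), knockout library 2 (0.147), MYCN-only library 2 (0.122) or MYCN-only library 3 (0.182), each a camera adjusted p.

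In all, 21 of the 40 lists passed camera with the preset correlation, 4 as higher and 17 as lower, and 0 passed with an estimated correlation or in fry's test of a shared direction. In fry's mixed test, which asks for change in either direction, 11 passed. Among them were glycolysis, p53 targets, T and natural killer lymphocytes and inflammatory cytokines, which did not pass camera. The cell cycle, ovary and intestine lists did not pass the mixed test (fry adjusted p = 0.168, 0.101 and 0.0502). The lists that did not pass camera had the following camera adjusted p. Mesenchymal transcription factors, testis and vascular endothelium each had 0.0501, glycolysis and MYC targets 0.066, p53 targets 0.0691, T and natural killer lymphocytes 0.125 and cadherins 0.22. Interrenal cells had 0.223, interferon 0.272, hepatocytes 0.297, pigment cells 0.431, oxidative phosphorylation 0.581, inflammatory cytokines 0.694, B lymphocytes 0.853 and neutrophils 0.89. Of the 19 lists that did not pass, 12 passed in camera with some 1 library left out, and 2 of them in both directions: oxidative phosphorylation as lower without knockout library 1 (adjusted p = 0.0204) and higher without knockout library 2 (0.00772), and hepatocytes as lower without MYCN-only library 1 (0.045) and higher without MYCN-only library 2 (0.000231). Vascular endothelium fell without knockout library 1 (0.000152) and rose with knockout libraries 2 and 3 left out (0.0326). Of the 21 calls, 12 passed in the same direction with knockout libraries 2 and 3 left out and 7 with the ovary list mean as a covariate. In 3 lists, none of which passed, the median and the camera direction differed in sign: noradrenergic identity, cadherins and neutrophils. For interrenal cells and B lymphocytes the mean log2 fold change (0.32 and 0.04) had the opposite sign to the median (-0.93 and -0.02) and to camera. The hepatocyte list mean spread most among the MYCN-only libraries, at 3.72, 8.14 and 6.64 log2 CPM in MYCN-only libraries 1, 2 and 3.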

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

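The fits with knockout libraries 2 and 3 left out, with the ovary covariate and with exact symbols were chosen after seeing the data. The ovary covariate fit rests mainly on knockout library 1, so it is not a check separate from leaving out knockout libraries 2 and 3. edgeR called 0 genes with DESeq2 size factors, upper-quartile factors, no low-count filter, a CPM filter and robust dispersion. A minimum fold change was applied to the calls of the main test, so its count of 0 was fixed in advance. DESeq2 called 1360 genes (850 higher, 510 lower), of which 1269 had an unadjusted edgeR p under 0.05, and limma-voom 1 (1 higher). Of the 105 genes named by the rule other than gas7a, 84 passed in DESeq2, 57 in edgeR without knockout library 1, 8 with the ovary covariate, 1 in limma-voom and 1 without MYCN-only library 2. Leaving out each library gave 0 to 1923 genes (0 to 1465 higher, 0 to 458 lower). With knockout libraries 2 and 3 left out there were 9 (9 higher), and with the ovary covariate 196 (159 higher, 37 lower). The numbers of the replicates did not pair the samples (correlations of same-numbered deviations -0.093, -0.153 and 0.190). Not every library correlated best with its own number. The replicate block gave 8 genes (8 higher) and 23 lists. gas7a stayed negative and short of the threshold under every alternative run, from -1.08 to -0.34 with libraries left out. Of the 40 lists, 19 to 27 passed under the alternatives, against 21, apart from 0 with an estimated correlation and 0 with fry. Of the 21 calls, 12 passed in the same direction with knockout libraries 2 and 3 left out (2 turned direction) and 7 with the ovary covariate (3 turned direction). With exact symbols 19 passed, and neuronal differentiation (camera adjusted p = 0.0531) and macrophages (0.193) were lost. Macrophages were also lost with the CPM filter (0.071). Upper-quartile factors moved the median log2 fold change of all genes from 0.04 to -0.14. Reversed were myca with limma-voom (-0.075) and without knockout library 1 (-0.32 to 0.69 over the libraries left out), and ccnb1 (-0.47) and ccnb2 (-1.19) with the ovary covariate. The first component held 71.9% over 500 genes and 54.7% over all genes. The causes were not tested.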

Other observations

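Genes for protein folding and secretion in the endoplasmic reticulum were higher in all 3 knockout libraries. The list was drawn up after 9 of its genes had been seen, so its count is not independent evidence. Of its 54 measured members, 50 were higher in knockout and 35 did so without overlap between libraries, among them the chaperone gene calr, at 383 ± 103 CPM against 123 ± 8.21 CPM (SD, n = 3), and the transcription factor gene xbp1, at 345 ± 73.1 against 104 ± 26.5 CPM. Without the 9 genes, 41 of 45 were higher, with a median log2 fold change of 0.85. Camera gave p = 1.86e-13 with a preset and p = 0.0499 with an estimated correlation, both unadjusted. These 45 genes are of the same pathway and libraries as the 9, so they are not independent evidence either. Vitellogenin genes, which encode egg yolk precursors made in the liver of females, were also higher in every knockout library. vtg1 was read at 25.7, 692 and 47580 CPM in knockout libraries 1, 2 and 3 and at 0.346 to 2.16 CPM in MYCN-only tumours. The labels give no sex. The genes calr, xbp1 and vtg1 were named after their values were seen.

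The tests of the cell cycle, the endoplasmic reticulum and the cleanly divided genes below were chosen after the results were seen, except the share around gas7a. The limit of the depth test was written down beforehand, but it was applied to a gene set chosen after the results were seen. The cell cycle list was higher in the libraries with ovary transcripts. Ovary tissue in the sampled tumour may account for it, since knockout library 1, with far less ovary RNA than knockout libraries 2 and 3 although more than the MYCN-only libraries, had a cell cycle mean 0.45 log2 CPM below the highest MYCN-only library (a difference of -0.45). An effect of the gas7 knockout on cycling in tumour cells cannot be told apart from this, because only 1 knockout library had an ovary mean near that of the MYCN-only libraries, and its cell cycle mean was not above them.

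The endoplasmic reticulum list had means of 6.67, 6.23 and 6.69 log2 CPM in knockout libraries 1, 2 and 3 and of 5.35, 5.5 and 5.44 in the MYCN-only libraries. Hepatocyte RNA of the kind in the MYCN-only libraries is argued against. Across those libraries the list mean ranged over only 0.15 log2 CPM while hepatocyte means ranged over 4.42. Yolk-producing liver cells stay open, because no MYCN-only library was rich in vitellogenin RNA. vtg1 reached at most 2.16 CPM in those libraries and at least 25.7 CPM in the knockout libraries. Ovary tissue cannot be told apart from genotype for this list, although knockout library 1 lay 1.17 log2 CPM above the highest MYCN-only library, since 1 library with less ovary RNA is too few. The sex of the fish and the handling of the groups stay open and untested.

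A set of 71 genes, 27 higher and 44 lower, divided the genotypes cleanly, with a range of at most 1 log2 unit within each genotype and a gap of at least 1 between them. This measure replaced an earlier count of genes read in every library of 1 genotype and in none of the other (9, against at most 2 in other splits), because most of those were read in knockout library 1 at far lower levels than in knockout libraries 2 and 3, and it was chosen with that result known. An exchange of knockout library 1 with a MYCN-only library is argued against, since the 3 splits that make it gave at most 20 such genes. When all libraries were thinned to the total of the shallowest, 57 of the 71 stayed cleanly divided. The division of those 57 thus did not need the extra reads of the deeper libraries. Thinning leaves the expected CPM unchanged, so genes chosen for a gap in CPM were likely to stay divided. It also cannot show a difference in preparation that goes with depth, so library depth stays open in that sense. A haplotype linked to gas7a is argued against as the whole cause, if gas7a is the mutated copy, since 1 of the 71 lay among the 200 tested neighbours of gas7a, and 19.5% of those neighbours had an unadjusted p under 0.05 against 19.2% of other genes. A haplotype linked to gas7b was not examined and stays open. So do a wrong genotype for knockout library 1 alone and a difference in handling between the groups. The sex of the fish and other tissue in the samples were not tested for these genes and stay open too. Among the 71 are the kidney list gene pax2a and 8 members of the endoplasmic reticulum list. The 71 genes may or may not follow from the knockout.

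The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. For genes past the threshold, the real split gave 0 (highest other 0), so 10 of 10 splits gave as many by construction and the comparison says nothing about chance. For lists past the threshold, 3 of 10 splits gave as many as the real 21, with 26 as the highest other. The 3 splits that keep knockout libraries 2 and 3 together, apart from knockout library 1, gave 26, 25 and 14 lists, and the other 6 gave 12 to 20. At an unadjusted p under 0.05 the real split had 2447 genes, those 3 had 1888, 1668 and 1267, and the other 6 had 163 to 430, which points to a structure of the libraries beside genotype. For cleanly divided genes, 1 of 10 splits, the real one, gave 71, and the highest other gave 20.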
